A study of Mus musculus with 12 samples.

How the data were processed

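Single-cell RNA-seq (10x Genomics droplets, in which every captured transcript carries a unique molecular identifier, UMI) was measured in cells from the liver and the blood of mice. The labels give 4 groups of 3 samples each: control blood, control liver, ethanol plus LPS blood and ethanol plus LPS liver. The count matrix of control liver replicate 1 was not used here, so control liver had 2 libraries and 11 libraries entered the work. Per the series text, blood and liver came from the same mouse, so libraries of one tissue stand for separate mice.

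The values are UMI counts per gene and barcode as the authors deposited them, with no normalization. Per the submitters' processing notes, reads were processed with Cell Ranger 6.1 against mm10. The deposited matrices held barcodes with at least 500 UMI each and 32285 genes. Gene coordinates are those of GENCODE M21 on GRCm38, matched by gene identifier. Cell annotations and read-level files were not used here. Results on some genes that the rule names, and a per-cell rule that used one of them, are not reported here. Before the samples were averaged, each pair of replicates was compared by a chi-square test of counts over genes, and every pair differed by more than sampling noise (45.3 to 563 times the degrees of freedom).

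Cells with at least 200 genes and at most 15% mitochondrial counts were kept, 63642 of 67647 barcodes. Doublets were scored per library with a Scrublet-type simulation (expected rate 6%). Automatic thresholds marked 0% to 8.87% of cells per library, so a score of at most 0.25 was required in every library after the automatic values had been seen. This left out 1846 doublets, 1.03% to 5.15% per library, and 61796 cells were used. Cells were clustered on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method at resolution 1.0, without batch integration, into 58 clusters. T and NK cells were clustered again among themselves into 29 clusters. Python 3.11.15 was used with scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9.

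Clusters were named from fixed markers and are written as "-like", since the names were rebuilt here and can differ from the authors' own. A name needed at least 3 markers detected in over 10% of the cluster's cells and no other class with more markers among the 10 leading genes. When T and NK cells were clustered again, the leading genes were compared only between T and NK classes. Markers of other classes, such as erythroid cells, could thus lead a named cluster. Such a cluster stayed unnamed where at least 3 markers of B-like, Kupffer cell-like or LSEC-like cells were each in over 30% of its cells. Clusters with mixed markers, or led by at least 3 cell cycle genes, stayed unnamed. So did those with a median UMI count below their library's median divided by 3 and no marker of the class among the 10 leading genes, while clusters of few UMI with such a marker kept their name. Conventional T clusters needed Cd8a and Cd8b1, or Cd4, in over 40% of cells and the other coreceptor in under 20%. These thresholds were set after the data were seen. In all, 50366 cells were named. The unnamed share was 10.3% ± 4.24 of cells in control blood (SD, n = 3), 23.0% ± 1.64 in control liver (n = 2), 16.6% ± 8.92 in treated blood (n = 3) and 31.0% ± 8.82 in treated liver (n = 3).

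Raw counts were summed over the cells of a class in a library, and libraries with under 20 cells of the class were left out. Sums were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. CPM are the summed counts scaled by the total of the sum. Each treatment contrast was fitted within a tissue, each tissue contrast within a treatment, and the tissue by treatment interaction over all 4 groups. Fixed gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Cell shares were tested with the same edgeR model on numbers of cells, with the named immune cells of the library as the offset, beside a two-sided exact permutation test that cannot go below 0.1 in these designs. A fold against a group with no UMI was computed against a floor of 3 counts over the group and is given as a lower bound. With 1 to 3 UMI in a group the ratio of pooled counts is given with its counting interval. These intervals and floors cover counting error only.

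The named genes were fixed by rule. For each main comparison they were Il15, Il15ra, Il2rb, Il2rg, Cxcr6, Cd69, Itgae and Itga1. They also included the 5 largest rises and the 5 largest falls among genes that passed, had a mean CPM of at least 20 and separated the groups without overlap, leaving out predicted gene models, mitochondrial, ribosomal, immunoglobulin and T cell receptor genes and markers of other cells. Up to 3 members of each fixed list with the smallest p completed them. For other classes 2 genes each way and Il15 were taken. The design, the rule, the lists, the markers and most alternatives were chosen before the data were examined.

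The tests were tested on simulated data with 200 genes changed by known folds. At a 2-fold change the LSEC comparison recovered 39% of the changed genes and at a 4-fold change 98%. For CD8 T-like cells of the liver the values were 21% and 85%, and for those of the blood 90% and 100%. False calls were 9.87% of calls in the LSEC simulation, 4.50% in the CD8 liver simulation and 6.86% in the CD8 blood simulation. For the interaction 12% and 78% were recovered. In the LSEC simulation 200 of 12893 genes changed, while the real comparison called 5352 of 13254. The recovery and false call rates thus describe settings with few changed genes.

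Whether shared replicate numbers pair the samples was checked from the correlation of deviations from the group means over CD8 T-like sums. Liver and blood of one number correlated at 0.458, 0.258 and 0.272 in treated mice and at 0.132 in the control mice, and the series text states that they are the same mice, so the numbers pair tissues. No label pairs control with treated mice, so in treatment contrasts a block is the shared number and not a mouse. Depth ranged from 42055796 to 143780000 UMI per library. Shares of cells with a UMI were given also after thinning each cell to 1000 UMI. Alternatives were other size factors, DESeq2 1.42.0, no filter on low counts, the mouse as a block, one fit of all groups, leaving out each library, doublets kept, stricter cell filters, clustering at resolution 2.0, sums thinned to the smallest total, at least 50 cells, other offsets for shares and, added after seeing the data, other doublet thresholds, excluded clusters put back and CD8 T cells taken by their own UMIs (any T or NK cell with Cd3e, Cd8a and Cd8b1 UMIs and no Cd4 UMI).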

Results

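The data describe single cells from the liver and the blood of mice in a model of alcohol-associated hepatitis, in which liver inflammation is brought on by alcohol and bacterial lipopolysaccharide (LPS). Per the labels, C57BL/6 mice of 10 weeks were acclimated for 5 days and given a diet with 5% ethanol by volume or a matched control diet. On day 11 they received 5 g/kg ethanol or maltose dextran by gavage, then 4 mg/kg LPS or saline 8 hours later, and tissue was taken 8 hours after that. Liver samples were sorted pools of 90000 CD45-positive leukocytes and 10000 CD146-positive liver sinusoidal endothelial cells (LSECs), which line the liver's capillaries, and blood samples were sorted CD45-positive mononuclear cells. Control blood had 3 libraries, with 81532352, 60058992 and 50837048 UMI from 7478, 6218 and 5487 barcodes. The control liver libraries used, replicates 2 and 3, held 68833856 and 97023384 UMI from 4417 and 7859 barcodes. Ethanol plus LPS ("treated") blood had 120069232, 42055796 and 143780000 UMI from 7284, 4010 and 10115 barcodes. Treated liver had 104375768, 60047048 and 57648344 UMI from 5740, 3187 and 5852 barcodes. Median UMI per barcode ranged from 6388 in treated liver replicate 3 to 14322 in treated liver replicate 2. Median mitochondrial percentages were 3.93 to 4.13 in control liver and 2.16 to 2.52 in treated liver. In blood they were 2.96 to 3.51 in control and 1.22 to 2.31 in treated mice.

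The first comparison asked which liver immune cells changed in their share of the named immune cells. Cell numbers per liver were not measured, and a change in any share moves the others. Neutrophil-like cells, short-lived phagocytes recruited in acute inflammation, rose from 1.26% ± 0.463 of the named immune cells in control liver (SD, n = 2) to 14.3% ± 3.97 in treated liver (n = 3), a log2 change of 3.52 ± 0.57 (SE) with an adjusted p of 0.000498. B-like cells, the antibody lineage, fell from 23.1% ± 3.63 to 6.39% ± 3.07 (log2 -1.86 ± 0.50, adjusted p = 0.0177). Plasmacytoid dendritic cell-like cells, known for interferon production, fell from 6.45% ± 0.551 to 1.97% ± 0.98 (log2 -1.73 ± 0.50, adjusted p = 0.0189). Kupffer cell-like cells, the resident liver macrophages, rose from 6.81% ± 2.42 to 15.6% ± 4.55, monocyte-like cells from 4.50% ± 0.849 to 10.2% ± 2.01 and CD8 T-like cells from 1.20% ± 0.199 to 3.64% ± 2.21, each with an adjusted p of 0.0445. CD4 T-like cells fell from 3.55% ± 0.829 to 1.58% ± 0.220 (adjusted p = 0.0445) and plasma cell-like cells from 1.84% ± 1.76 to 0.478% ± 0.243 (adjusted p = 0.0424). Basophil or mast cell-like cells rose from 2 to 31 cells (adjusted p = 0.0312). Shares of conventional dendritic cell-like (log2 0.26, adjusted p = 0.643), NK or ILC1-like (log2 -0.05, adjusted p = 0.914) and NKT-like cells (log2 -0.34, adjusted p = 0.549) did not pass. LSEC-like cells, added at a fixed number, were 1835 in control and 890 in treated liver and stayed out of the shares, as the CD45 sort stands behind all others. The exact permutation p was 0.1 for neutrophil-like, B-like, plasmacytoid, CD4 T-like and monocyte-like shares, the smallest that 2 against 3 libraries allow, and 0.2 to 0.3 for the rest that passed.

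Only the neutrophil-like rise passed without each library in turn. Without control liver replicate 3 the B-like share gave an adjusted p of 0.0834, the plasmacytoid share 0.0834, the basophil share 0.0897, the CD4 T-like share 0.132, the CD8 T-like share 0.129, the Kupffer share 0.393 and the monocyte share 0.360. Without control liver replicate 2 the plasmacytoid share gave 0.105, CD4 T-like 0.361, CD8 T-like 0.196, Kupffer 0.172, monocyte 0.196 and plasma cells 0.793. Without treated liver replicate 3 the CD4 T-like share gave 0.209, CD8 T-like 0.133, Kupffer 0.209, monocyte 0.133 and the plasmacytoid share 0.105. Without treated liver replicate 1 the CD4 T-like and monocyte shares gave 0.0848 each and Kupffer 0.0823, and without replicate 2 CD8 T-like gave 0.162 and plasma cells 0.138. With neutrophils left out of the denominator the CD4 T-like (log2 -0.97) and plasma cell shares (log2 -1.66) did not pass (adjusted p = 0.0635 each). Different clusters held most of some classes in the 2 groups: neutrophil-like cells were in cluster 31 in control liver and in clusters 4 and 5 in treated liver. Kupffer cell-like cells were in clusters 40 and 51 against 14 and 44, and CD8 T-like cells in clusters 2, 6 and 11 against 1 and 3 of the separate clustering of conventional T cells. Monocyte-like cells were in cluster 24, led by Adgre4 and Ace, in control liver and in cluster 9, led by Arg1 and F13a1, in treated liver. Conventional dendritic cell-like cells were mostly in cluster 42, led by Cd209a, against cluster 34, led by Fscn1. B-like cells were mostly in clusters 1 and 18 against 3. In the clustering of T and NK cells, NK or ILC1-like cells were mostly in clusters 9 and 6 against 8 and 2 and NKT-like cells in 0 against 1 and 5. CD4 T-like cells were also in different clusters of conventional T cells, and in blood the same classes other than Kupffer cell-like cells also lay mostly in different clusters in the 2 groups. Clusters kept out of a class by the naming thresholds held 16.4% of B-like cells in control liver and 0.769% in treated liver, and 12.5% and 0.775% of CD4 T-like cells. They held 0.105% and 24.2% of NKT-like cells, and 35.2% of LSEC-like cells in treated liver.

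**Figure D1:**
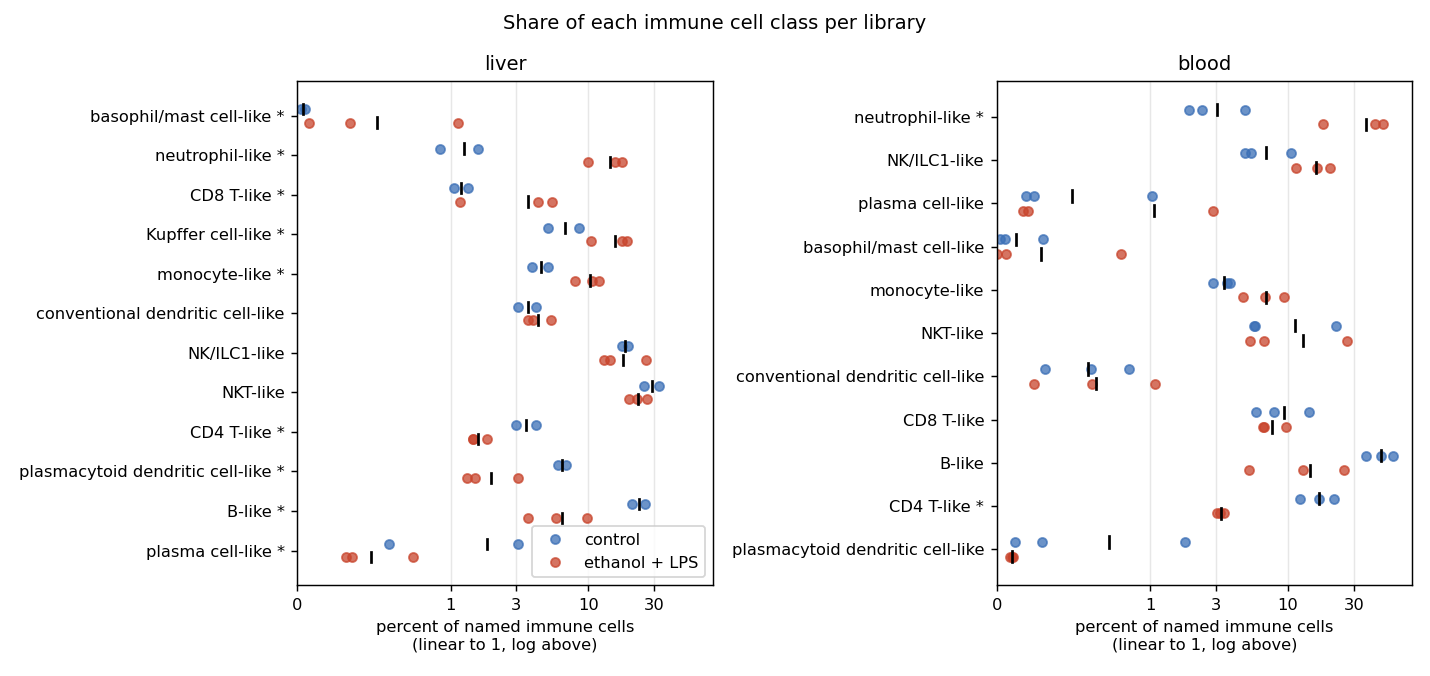
Share of each named class among the named immune cells of a library (percent, log scale that is linear near 0), one point per library, for control and treated liver and blood. The short line is the group mean and an asterisk marks an adjusted p under the threshold; neutrophil-like cells rose from 1.26% to 14.3% in liver and from 3.06% to 36.6% in blood.

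In blood the same question gave 2 of 11 classes past the threshold. The blood samples were mononuclear cell preparations, so these shares describe that fraction and not whole blood. Neutrophil-like cells rose from 3.06% ± 1.60 to 36.6% ± 16.6 (SD, n = 3 each; log2 3.58 ± 0.68, adjusted p = 0.0082). CD4 T-like cells, the helper lineage, fell from 16.9% ± 4.61 to 3.25% ± 0.198 (log2 -2.38 ± 0.46, adjusted p = 0.0082). B-like cells were 47.2% ± 10.6 and 14.6% ± 10.3 (adjusted p = 0.107), NK or ILC1-like cells 6.91% ± 3.07 and 16.0% ± 4.35 (adjusted p = 0.123). Monocyte-like cells were 3.43% ± 0.491 and 6.96% ± 2.36 (adjusted p = 0.127), and plasmacytoid cells 0.732% ± 0.911 and 0.0957% ± 0.00988 (adjusted p = 0.105). Without control blood replicate 3 the neutrophil and CD4 T-like calls were lost (adjusted p = 0.0534 each). The CD4 T-like call was also lost without treated blood replicate 1 (0.0966) and with neutrophils left out of the denominator (log2 -1.71, adjusted p = 0.0715). The tissue by treatment interaction of the shares, tested with edgeR after the data were seen, had no adjusted p below 0.319.

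The series title names the cytokine Il15, which sustains NK cells and memory CD8 T cells, as a signal from LSECs, so its level was set out by cell class. Il15 (ENSMUSG00000031712, GRCm38 chromosome 8, 82331632 to 82403222, minus strand) was highest in neutrophil-like cells of control liver at 454 ± 120 CPM (SD, n = 2), where it ranked first of the classes in each library. It fell there to 80.6 ± 11.7 CPM in treated liver (n = 3; log2 -1.76 ± 0.29, adjusted p = 0.00299). Il15 UMIs per neutrophil-like cell went from 2.07 ± 0.676 to 0.815 ± 0.123, as the total UMI of such a cell went from 4517 ± 299 to 10112 ± 360, values that were not tested. In monocyte-like cells, of which control and treated ones lay in clusters 24 and 9, it fell from 48.1 ± 15.9 to 6.59 ± 1.34 CPM (log2 -2.62 ± 0.28, adjusted p = 0.00014). Per monocyte-like cell Il15 UMIs went from 0.623 ± 0.239 to 0.222 ± 0.0340. The total UMI of such a cell went from 12830 ± 742 to 34273 ± 6468, and these values were not tested. In B-like cells Il15 rose from 2.46 ± 0.313 to 14.9 ± 7.79 CPM (log2 2.71 ± 0.52, adjusted p = 0.00126), and in NKT-like cells from 2.82 ± 0.74 to 9.76 ± 5.07 CPM (log2 1.92 ± 0.45, adjusted p = 0.0104). LSEC-like cells held 62.2 ± 0.431 and 38.5 ± 22.8 CPM (log2 -0.62 ± 0.49, adjusted p = 0.345), rank 3 to 4 in control and 3 to 6 in treated liver. Il15 UMIs per LSEC-like cell were 0.682 ± 0.0977 and 0.694 ± 0.470 as the total UMI of such a cell went from 10971 ± 1648 to 17633 ± 5178, also not tested. Kupffer cell-like cells held 93.8 ± 22.7 and 32.5 ± 25.3 CPM (adjusted p = 0.23). Conventional dendritic cell-like cells held 50.3 ± 22.7 and 92.3 ± 50.5 CPM (adjusted p = 0.187, but 0.0337 without treated liver replicate 2 and 0.0473 at resolution 2.0) and CD8 T-like cells 1.81 and 1.68 CPM. The neutrophil call was lost without control liver replicate 2 (log2 -1.32, adjusted p = 0.0727), the NKT-like call without control liver replicate 2 (0.0801) or 3 (0.0577). All but the B-like call were lost with sums thinned to the smallest library (adjusted p = 0.613 in neutrophil-like, 0.0608 in monocyte-like and 0.0606 in NKT-like cells). In blood Il15 also fell in neutrophil-like (351 ± 110 to 60.2 ± 9.98 CPM, log2 -1.96 ± 0.28), monocyte-like (log2 -2.11 ± 0.38) and NK or ILC1-like cells (log2 -1.59 ± 0.35, adjusted p = 0.0036). It rose in B-like cells (log2 2.16 ± 0.48, adjusted p = 0.00512), although thinning ended the B-like (adjusted p = 0.776) and NK calls (0.129). It also rose in conventional dendritic cell-like cells (log2 2.16 ± 0.40, adjusted p = 0.00438), a call lost without control blood replicate 2 (0.0629) or 3 (0.0749). In NKT-like cells it rose by log2 1.21 ± 0.44 (adjusted p = 0.0421), a call lost without control blood replicate 2 (0.206) or 3 (0.104) or treated blood replicate 3 (0.537), with DESeq2 (0.0932), with the replicate as a block (0.108), in one fit of all groups (0.0582), at resolution 2.0 (0.307) and with excluded clusters put back (0.205).

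**Figure D2:**
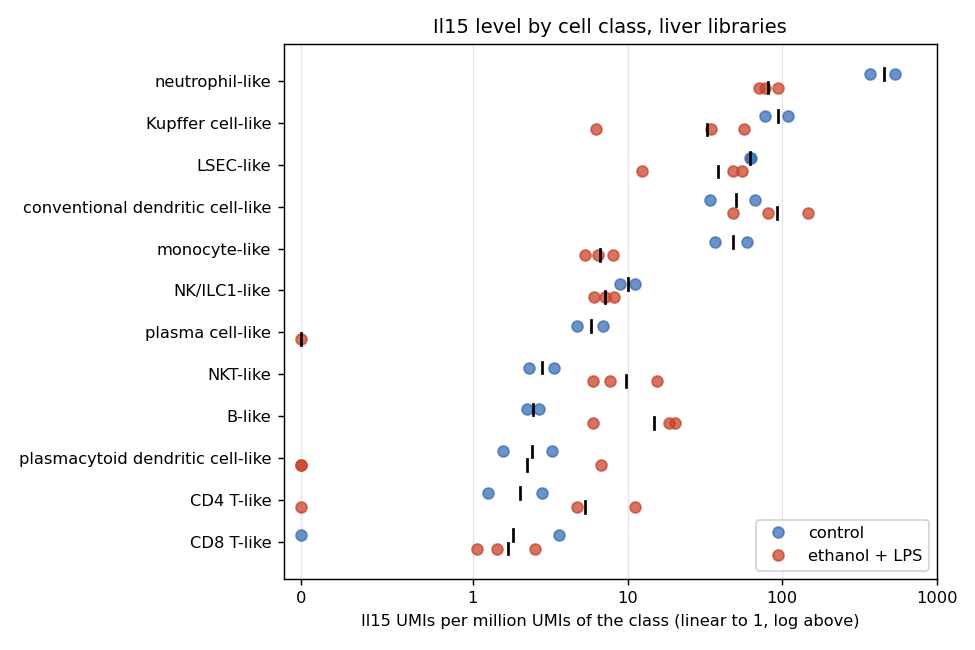
Il15 in CPM of the summed UMI of each class in liver (log scale that is linear near 0), one point per library, control against treated. Neutrophil-like cells were highest in control liver at a mean of 454 CPM, and LSEC-like cells had means of 62.2 and 38.5 CPM.

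LSEC-like cells were then compared between treated and control liver, as the title places the signal in these cells. Treated LSEC-like cells carried high levels of transcripts that control cells lacked. Npy, a neuropeptide, was at least 1935-fold higher at 285 ± 109 CPM (SD, n = 3) against 0 of the pooled UMI (n = 2). Ch25h, which makes the immune-active oxysterol 25-hydroxycholesterol, rose from 0.256 to 1361 ± 334 CPM (log2 12.43 ± 0.47). The chemokine genes Cxcl9 (125 ± 48.0 to 7100 ± 2453 CPM, log2 5.94 ± 0.45) and Cxcl10 (37.8 ± 2.95 to 3626 ± 728 CPM, log2 6.71 ± 0.28), whose products draw Cxcr3-bearing T cells, rose as well. Among the falls were Cd300lg, an endothelial receptor (521 ± 67.1 to 4.69 ± 1.58 CPM, log2 -6.49 ± 0.25), Btnl9 (360 to 3.55 CPM, log2 -6.08 ± 0.42), Itga8 (log2 -6.11 ± 0.62) and Ncald (log2 -7.15 ± 0.64). Of 13254 genes tested, 5352 passed, 2502 higher and 2850 lower (6617 at an unadjusted p under the threshold), with 75 to 1064 cells per library. Treated LSEC-like cells lay in cluster 23 (99.7%) and control ones in clusters 12 (75.2%) and 35 (24.7%). The count was 2599 without control liver replicate 2, 2278 without replicate 3 and 1205 with sums thinned to the smallest library, of which 1181 were among the 5352.

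On the Il15 receptor side, Il2rg (ENSMUSG00000031304, chromosome X, 101264378 to 101268255), the shared gamma chain, rose in LSEC-like cells from 11.3 ± 1.42 to 54.9 ± 4.20 CPM (log2 2.43 ± 0.21, adjusted p = 0.000199). Il15ra (ENSMUSG00000023206, chromosome 2, 11705290 to 11734317), which presents Il15 to neighbouring cells, rose from 20.8 ± 4.04 to 45.4 ± 17.8 CPM (log2 1.19 ± 0.30, adjusted p = 0.0164). Socs1, a brake on cytokine signalling, rose (log2 3.64 ± 0.31, 15.8 to 185 CPM). Of the 12 IL-15 axis genes tested 4 rose and 1 fell, also adjusted over the list alone, and the list did not pass (adjusted p = 0.148). The Il15ra call was lost without control liver replicate 2 (log2 1.04, adjusted p = 0.123), without replicate 3 (log2 1.41, adjusted p = 0.0616) and in thinned sums (log2 1.53, adjusted p = 0.117). Thinning also ended the Il2rg call (log2 1.24, adjusted p = 0.205). Il2rb was 7.11 and 16.4 CPM (adjusted p = 0.138, but 0.0451 without treated liver replicate 1). Itga1 was 1081 ± 154 and 598 ± 203 CPM (log2 -0.72, adjusted p = 0.0808, but 0.00898 without treated liver replicate 2). In treated liver Il15ra was highest outside LSECs, at 264 ± 111 CPM in Kupffer cell-like cells (12.7 ± 4.93 in control). It was 183 ± 84.6 CPM in conventional dendritic cell-like cells (28.2 ± 6.31 in control). It rose in both, by log2 4.88 ± 0.52 (adjusted p = 0.000397) and 2.78 ± 0.47 (adjusted p = 0.0054), tests that were not repeated without each library.

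Inflammatory gene lists rose in LSEC-like cells. Interferon-stimulated genes rose in 22 of 24, also 22 adjusted over the list alone, among them Gbp2 (log2 5.06 ± 0.24) and Igtp (log2 4.97 ± 0.20), 2 GTPases of cell-autonomous defence, and Zbp1 (log2 5.51 ± 0.25), a nucleic acid sensor. The list had an adjusted p of 2.45e-26 (adjusted p = 0.186 with an estimated correlation). Of 24 genes of the NF-kB and LPS response 19 rose and 1 fell (20 and 1 adjusted over the list alone), led by the acute-phase gene Saa3 (0.299 to 651 CPM) and the monocyte chemokine Ccl2 (1.59 to 2001 CPM). Saa3 was 42510 CPM in monocyte-like cells of treated liver and 222 CPM in B-like, 289 in NK or ILC1-like and 237 in NKT-like cells, so part of the LSEC-like level may be RNA from other cells. The list passed at an adjusted p of 7.31e-19 (adjusted p = 0.186 with an estimated correlation). Chemokine genes rose in 11 of 12 (11 adjusted over the list alone; adjusted p = 3.55e-15, adjusted p = 0.0732 with an estimated correlation). Adhesion and recruitment genes rose in 12 of 15 (12, with 1 lower, adjusted over the list alone), such as Selp, the selectin that lets leukocytes roll (log2 6.07 ± 0.40). For the list the adjusted p was 1.81e-10 (adjusted p = 0.0732 with an estimated correlation). MHC class I presentation genes rose in 13 of 15 (14 adjusted over the list alone), among them the peptide transporter Tap1 (log2 3.52 ± 0.20) and the transactivator Nlrc5 (log2 3.01 ± 0.23). As a list they had an adjusted p of 3.8e-09 (adjusted p = 0.0732 with an estimated correlation). In the MHC class II list, which did not pass (adjusted p = 0.0629, but 0.0432 without control liver replicate 3 and 0.00135 without treated liver replicate 2), the checkpoint ligand Cd274 (log2 5.03 ± 0.28) and Cd40 (log2 2.94 ± 0.41) rose. All 13 glycolysis and hypoxia genes rose, led by the glucose transporter Slc2a1 (log2 7.24 ± 0.39) and Hif1a (log2 4.02 ± 0.24). Their list had an adjusted p of 2.95e-14 (adjusted p = 0.208 with an estimated correlation). Immediate early and heat shock genes rose in 12 of 16 (13 adjusted over the list alone), such as Atf3 (log2 4.67 ± 0.41) and Junb (log2 2.78 ± 0.22). This list gave an adjusted p of 5.27e-06 (adjusted p = 0.223 with an estimated correlation).

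Genes of the scavenging endothelium fell. Of 18 LSEC identity genes 15 fell and 1 rose, also adjusted over the list alone, among them the mannose receptor Mrc1 (2499 to 137 CPM, log2 -4.04 ± 0.25), Ehd3 (2524 to 79.8 CPM, log2 -4.86 ± 0.22) and coagulation factor F8 (log2 -2.57 ± 0.21). The list passed at an adjusted p of 1.95e-11 (adjusted p = 0.186 with an estimated correlation); several members also served to name the class. Of 11 genes that vary between the portal and central ends of the sinusoid 8 fell and 1 rose (9 and 1 adjusted over the list alone): Cdh13 (log2 -4.35 ± 0.20) and the central angiocrine factor Wnt2 (log2 -3.60 ± 0.33) fell while thrombomodulin, Thbd, rose (log2 3.29 ± 0.24). For the list the adjusted p was 0.000215 (adjusted p = 0.186 with an estimated correlation). Coagulation and vascular tone genes went both ways, 7 higher and 4 lower of 15, also adjusted over the list alone, and Angpt2, which destabilises vessels, rose (log2 3.96 ± 0.28; list adjusted p = 0.00263, adjusted p = 0.484 with an estimated correlation). Of 6 alcohol metabolism genes 5 fell, also adjusted over the list alone, such as the acetaldehyde-clearing Aldh2 (log2 -2.95 ± 0.21). As a list they had an adjusted p of 0.00263 (adjusted p = 0.25 with an estimated correlation). In the antioxidant and metal list 8 of 12 rose and 2 fell, also adjusted over the list alone: the metallothionein Mt2 rose (log2 6.04 ± 0.30) and the iron exporter Slc40a1 fell (log2 -3.13 ± 0.20). Their list had an adjusted p of 0.000276 (adjusted p = 0.186 with an estimated correlation). Beside these, markers of other cells moved in LSEC-like sums: 6 of 6 neutrophil markers rose (adjusted p = 0.00107, adjusted p = 0.227 with an estimated correlation), among them S100a9 (log2 4.03 ± 0.82). The T and NK marker Ccl5 rose (log2 3.18 ± 0.64) and the B cell marker Cd79a fell (log2 -2.65; adjusted p = 0.205 without control liver replicate 3). Of 17 cytotoxicity genes 9 rose (9, with 1 lower, adjusted over the list alone; adjusted p = 0.0089, adjusted p = 0.577 with an estimated correlation). Of 9 mitochondrially encoded genes, a sign of RNA quality, 5 fell (6 adjusted over the list alone), such as mt-Nd4 (log2 -1.04; adjusted p = 0.0767 without control liver replicate 2 and 0.0688 without replicate 3). The list did not pass (adjusted p = 0.0629, though 0.0437 without control liver replicate 3 and 0.0169 without treated liver replicate 2).

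**Figure D3:**
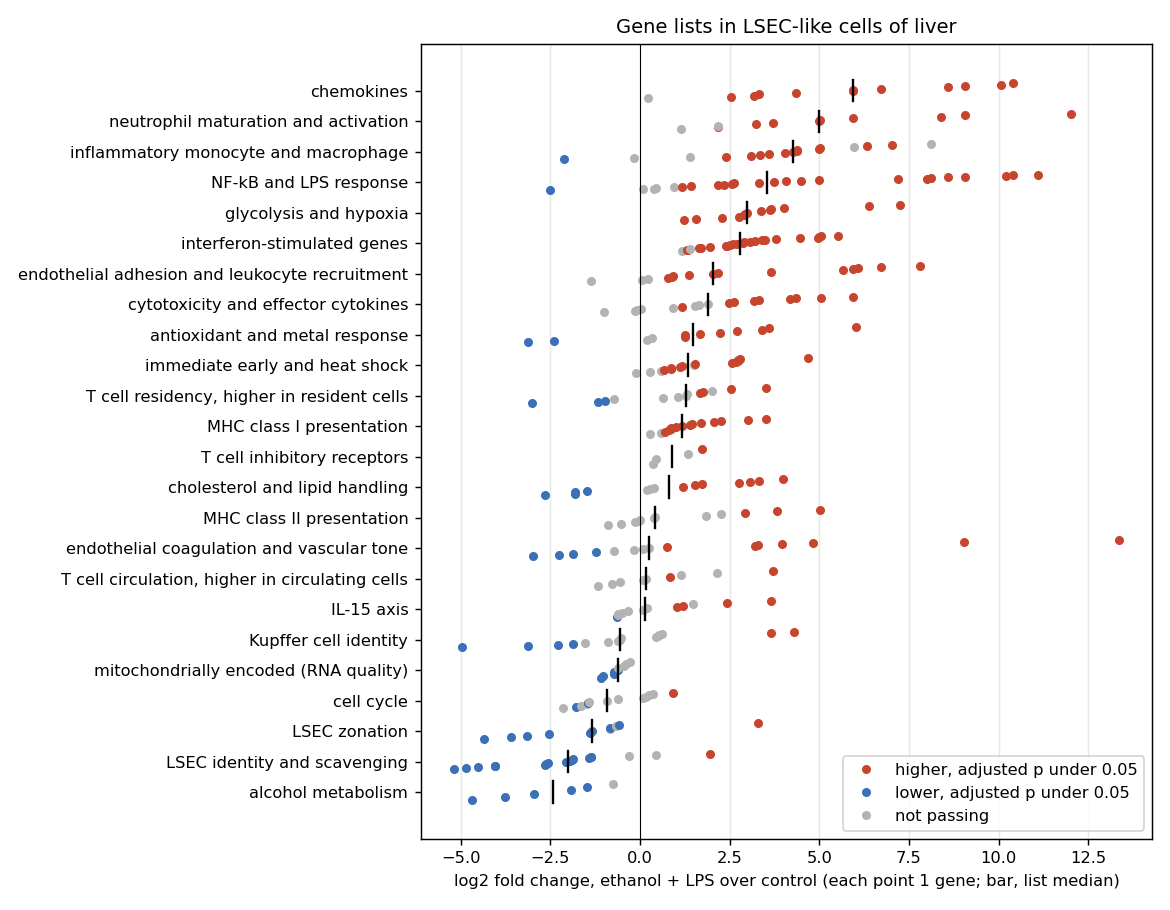
Log2 fold change, treated against control, of each tested gene of the fixed lists in LSEC-like cells of the liver; dots are genes and bars list medians. The chemokine list has a median of 5.94 and the LSEC identity list one of -2.01.

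CD8 T-like cells of the liver were compared because the title names resident memory CD8 T cells. The class held few cells with a residency profile. At least 3 of the fixed residency markers had UMIs in 11.3% ± 3.33 of its cells in control liver. In treated liver they did in 13.9% ± 11.2. Among control liver CD8 T cells taken by their own UMIs the share was 44.6% ± 9.56. The contrast thus describes mostly other CD8 T cells and not resident memory cells as such. The granule protease Gzmb, a killing effector, had 2247 UMI in treated (828 ± 251 CPM, SD, n = 3) and 1 in control cells (n = 2), a ratio of 705 (counting interval 126 to 27853). Gzmb UMIs were also in 39.7% of B-like cells of treated liver, a class that should lack them. They were in 61.9% of CD8 T-like cells of treated blood and liver together. Part of the Gzmb level may thus be RNA from other cells, and that part was not measured. Il2rb (ENSMUSG00000068227, chromosome 15, 78479256 to 78495271), the signalling chain of the Il15 receptor, rose from 121 ± 38.4 to 504 ± 126 CPM (log2 1.88 ± 0.32, adjusted p = 0.00167). Itgae (ENSMUSG00000005947, chromosome 11, 73090583 to 73147446), which encodes the CD103 integrin, fell from 69.2 ± 9.38 to 6.52 ± 4.89 CPM (log2 -3.65 ± 0.50, adjusted p = 0.000453). Its level in CD8 T-like cells of control blood was 64.0 ± 14.7 CPM, so Itgae did not set control liver cells apart from blood cells. Cxcr6 (ENSMUSG00000048521, chromosome 9, 123806475 to 123811760), the receptor that holds T cells in the liver sinusoids, fell from 68.8 ± 30.8 to 20.2 ± 8.47 CPM (log2 -2.0 ± 0.41, adjusted p = 0.00543). Cd69 (ENSMUSG00000030156, chromosome 6, 129267325 to 129275436), an early activation and residency marker, rose from 162 ± 87.3 to 442 ± 136 CPM (log2 1.36 ± 0.36, adjusted p = 0.0244). Itga1 (ENSMUSG00000042284, chromosome 13, 114953096 to 115101964), a collagen-binding integrin, fell from 18.9 ± 1.20 to 3.93 ± 2.14 CPM (log2 -2.38 ± 0.69, adjusted p = 0.038). Il15ra (log2 1.17 ± 0.56, adjusted p = 0.207) and Il2rg (log2 0.31 ± 0.25, adjusted p = 0.495) did not pass. The crosslinking enzyme Tgm2 was at least 21.5-fold and the receptor gene Lilr4b at least 23.6-fold higher than in control cells, which had no UMI of either. The selenium transporter Selenop (log2 -4.40 ± 0.58), Clybl (log2 -4.79 ± 0.56) and Lypd6b (log2 -4.28 ± 0.49) fell. Of 7568 genes 816 passed, 376 higher and 440 lower (1904 unadjusted), from 22 to 125 cells and 276879 to 1182562 UMI per library.

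Several of these calls rested on single libraries or on depth. Without control liver replicate 3, 276 genes passed and Cxcr6 (log2 -1.33, adjusted p = 0.265), Cd69 (log2 0.88, adjusted p = 0.349) and Itga1 (log2 -2.26, adjusted p = 0.43) did not. Without control liver replicate 2 (412 genes) Itga1 (adjusted p = 0.192) did not pass, nor without treated liver replicate 3 (0.0945), and without treated liver replicate 1 the count was 1239. In thinned sums 199 genes passed, and Il2rb (log2 1.66, adjusted p = 0.0534), Itgae (log2 -3.04, adjusted p = 0.0693), Cxcr6 (adjusted p = 0.115) and Cd69 (adjusted p = 0.0853) fell short. With at most 10% mitochondrial counts 405 genes passed and Itga1 did not (adjusted p = 0.19). Itga1 was also lost with DESeq2 (adjusted p = 0.181), with at least 50 cells (0.104), at resolution 2.0 (0.0799) and at a doublet score of 0.15 (0.0515). Cxcr6 was lost at resolution 2.0 (log2 -1.02, adjusted p = 0.233) and when CD8 T cells were taken by their own UMIs (log2 -0.77, adjusted p = 0.0986).

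By list, CD8 T-like cells of the liver gained effector and interferon genes. Cytotoxicity and effector genes rose in 10 of 17 (12 adjusted over the list alone), such as Gzma (13.2 to 555 ± 382 CPM, log2 4.88 ± 0.70). This list gave an adjusted p of 2.86e-11 (adjusted p = 0.206 with an estimated correlation). Interferon-stimulated genes rose in 18 of 23 (20 adjusted over the list alone), among them Gbp2 (27.5 to 607 CPM, log2 4.28 ± 0.53). The list passed at an adjusted p of 1.08e-19 (adjusted p = 0.206 with an estimated correlation). IL-15 axis genes rose in 4 of 11, also adjusted over the list alone, including the feedback inhibitors Socs1 (35.9 to 238 CPM, log2 2.52 ± 0.32) and Cish (157 against 3 UMI, ratio 16.4, counting interval 5.52 to 80.5). For the list the adjusted p was 0.00194 (adjusted p = 0.206 with an estimated correlation). Circulation genes fell in 4 of 9 (5 adjusted over the list alone), among them Klf3 (log2 -2.01 ± 0.29) and Lef1 (log2 -1.63 ± 0.25), transcription factors of quiescent T cells. As a list they had an adjusted p of 0.00204 (adjusted p = 0.206 with an estimated correlation). Residency genes split, 4 higher and 4 lower of 12 (6 and 4 adjusted over the list alone), and the list did not pass (adjusted p = 0.497). Of 15 NF-kB and LPS response genes 8 rose (9 adjusted over the list alone), such as Nfkbiz (log2 2.45 ± 0.40). Their list had an adjusted p of 2.57e-09 (adjusted p = 0.206 with an estimated correlation), and of 15 MHC class I genes 7 rose (12 adjusted over the list alone), such as Psme1 (log2 1.56 ± 0.24; adjusted p = 6.73e-07, adjusted p = 0.206 with an estimated correlation). Of 9 mitochondrially encoded genes 7 fell (9 adjusted over the list alone; adjusted p = 5.56e-06, adjusted p = 0.206 with an estimated correlation), such as mt-Cytb (log2 -0.97 ± 0.16). Markers of other cells moved too: 3 of 3 neutrophil markers rose (adjusted p = 4.52e-05, adjusted p = 0.206 with an estimated correlation), with S100a9 at 3.29 and 166 ± 166 CPM (log2 5.04 ± 1.00, but 0.05 in CD8 T cells taken by their own UMIs). Of 3 B cell markers 2 fell (adjusted p = 0.000631, adjusted p = 0.206 with an estimated correlation).

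The same contrast in CD8 T-like cells of the blood, with 3 libraries a group, passed for 3361 of 10876 genes, 1522 higher and 1839 lower (4523 unadjusted; 186 to 821 cells and 1819763 to 11301113 UMI per library). Gzmb rose from 1.75 to 1023 ± 544 CPM (log2 9.21 ± 0.59, n = 3). The interferon gamma gene Ifng rose by log2 9.60 ± 1.15 and the high-affinity IL-2 receptor chain Il2ra by log2 7.28 ± 0.70. RNA from other cells may be part of these levels too, and that part was not measured. Il2rb rose from 94.3 ± 18.3 to 411 ± 121 CPM (log2 1.97 ± 0.23, adjusted p = 8.5e-05). Cd69 rose from 99.8 to 332 CPM (log2 1.59 ± 0.18, adjusted p = 7.69e-05) and Il15ra from 7.27 ± 0.715 to 23.6 ± 11.9 CPM (log2 1.63 ± 0.31, adjusted p = 0.00209; 0.0838 in thinned sums). Itgae fell from 64.0 ± 14.7 to 3.93 ± 0.613 CPM (log2 -4.12 ± 0.24, adjusted p = 8.46e-07). Cxcr6 fell from 28.9 ± 1.58 to 13.975 ± 3.28 CPM (log2 -1.16 ± 0.19, adjusted p = 0.000795), although in CD8 T cells taken by their own UMIs the Cxcr6 change was log2 0.17 (adjusted p = 0.675). Actn2 (log2 -4.12 ± 0.24), Ntrk3 (log2 -4.08 ± 0.21) and Dapl1, a gene of naive T cells (log2 -3.58 ± 0.35), also fell. Il2rg (log2 0.19, adjusted p = 0.348) and Itga1 (log2 0.58, adjusted p = 0.436) did not pass. The count was 2190 without control blood replicate 1 and 1275 in thinned sums.

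Of 26 fixed lists tested in blood CD8 T-like cells 16 passed at the preset correlation, 12 of them upward, and 0 with an estimated correlation. IL-15 axis genes rose in 6 and fell in 1 of 11, also adjusted over the list alone, led by Cish (log2 4.59 ± 0.38) and Socs1 (log2 2.85 ± 0.26). This list gave an adjusted p of 0.000198 (adjusted p = 0.0853 with an estimated correlation). Residency genes rose in 9 and fell in 4 of 15, also adjusted over the list alone, with Ahr (log2 4.02 ± 0.29) and the chemokine Xcl1 (log2 3.31 ± 0.33) higher and Itgae and Cxcr6 lower (adjusted p = 0.00244, adjusted p = 0.217 with an estimated correlation). Cytotoxicity genes rose in 12 and fell in 2 of 17 (14 and 2 adjusted over the list alone; adjusted p = 5.43e-14, adjusted p = 0.093 with an estimated correlation), among them Gzma (log2 6.29 ± 0.48) and the death ligand Fasl (log2 3.61 ± 0.30). Inhibitory receptor genes rose in 7 and fell in 1 of 8, also adjusted over the list alone, among them Ctla4 (log2 2.58 ± 0.18) and the ectonucleotidase Entpd1 (log2 2.57 ± 0.29). The list passed at an adjusted p of 4.58e-07 (adjusted p = 0.0599 with an estimated correlation). Interferon-stimulated genes rose in 22 of 23 (23 adjusted over the list alone; adjusted p = 7.9e-41, adjusted p = 0.0853 with an estimated correlation), such as Oasl2 (log2 4.33 ± 0.25) and Gbp5 (log2 3.41 ± 0.18). Of 6 neutrophil markers 6 rose in these sums (adjusted p = 4.59e-12, adjusted p = 0.0853 with an estimated correlation), S100a8 from 7.75 to 241 ± 108 CPM. All 6 of 6 B cell markers tested fell (adjusted p = 1.39e-07, adjusted p = 0.0599 with an estimated correlation), Cd79a by log2 -3.73 ± 0.28. Mitochondrially encoded genes fell in 6 of 9 (8 adjusted over the list alone; adjusted p = 0.0271, adjusted p = 0.549 with an estimated correlation), a call lost without control blood replicate 2 (0.0562) or treated blood replicate 1 (0.0713).

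**Figure D4:**
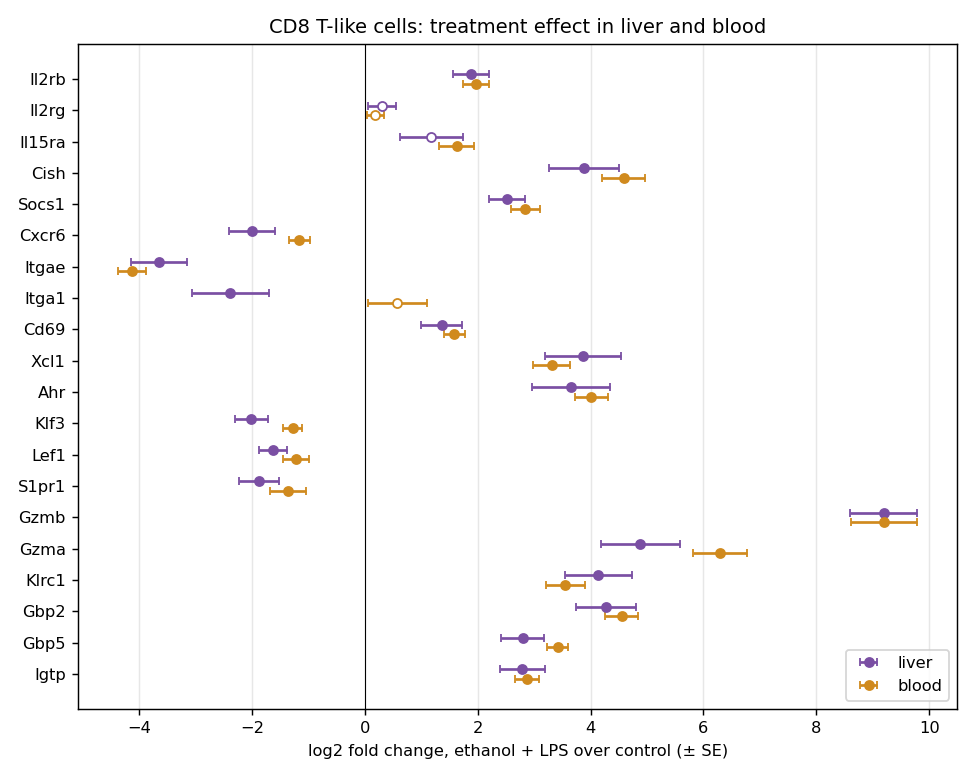
Log2 fold change ± SE, treated against control, of named genes in CD8 T-like cells of the liver (n = 2 and 3) and the blood (n = 3 and 3); open symbols did not pass the threshold. Il2rb was 1.88 and 1.97 and Itgae -3.65 and -4.12 in liver and blood.

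The treatment effects of liver and blood were then set side by side; their libraries came from the same mice. Over 7563 genes tested in both, 347 were higher in both tissues, where independent lists of 372 and 1264 genes would share 62.2. In the other direction 413 were lower in both, where lists of 440 and 1196 would share 69.6. No gene passed in opposite directions. With edgeR the interaction, which tests whether the effect differed between tissues, passed for 0 of 9981 genes; 410 had an unadjusted p under the threshold, DESeq2 called 2 and the fit with the mouse as a block 9. The interaction of Itga1 was log2 -2.96 ± 0.91 (adjusted p = 1.00), of Cxcr6 -0.84 ± 0.44 and of Il2rb -0.07 ± 0.40.

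The tissue contrast asked which CD8 T-like genes differed between liver and blood of one treatment. In control mice 4 of 10667 genes passed (923 unadjusted): Maf, a transcription factor of effector and resident T cells, was higher in liver (1.25 against 60.3 ± 78.2 CPM, log2 5.34 ± 0.87, adjusted p = 0.0464) and so was Chn2 (log2 2.56), which lies outside the rule and was chosen after its values were seen. Maf is also an LSEC identity gene, and the LSEC marker Stab2 was 25.3 and 3.29 CPM in the CD8 T-like sums of control liver replicates 2 and 3 against at most 0.445 CPM in control blood. By the lowest of the 5 most abundant LSEC markers, a comparison added after the results were seen, LSEC RNA can bring at most 16.5 of 115.6 CPM of Maf in replicate 2 (Stab2) and 0.992 of 4.94 CPM in replicate 3 (Ptprb), so LSECs may bring part of the Maf level. The immediate early gene Junb (288 against 59.7 CPM, log2 -2.25 ± 0.33) and the chaperonin subunit Cct6a (233 against 111 CPM, log2 -1.16 ± 0.18) were lower (adjusted p = 0.0395 each). Itgae was 64.0 ± 14.7 CPM in blood and 69.2 ± 9.38 in liver (log2 0.03 ± 0.27, adjusted p = 0.999). Cxcr6 was 28.9 ± 1.58 CPM in blood and 68.8 ± 30.8 in liver (log2 1.32 ± 0.25, adjusted p = 0.117), and Itga1 1.65 ± 1.23 and 18.9 ± 1.20 (log2 3.50 ± 0.68, adjusted p = 0.128). With the mouse as a block Cxcr6 (adjusted p = 0.00308) and Itga1 (adjusted p = 0.0447) passed, and with DESeq2 too (0.0122 and 0.00534). They also passed without control blood replicate 2 (adjusted p = 0.021 each) or 3 (0.0457 and 0.0404). Residency genes as a list were higher in liver (adjusted p = 2.2e-05, adjusted p = 0.441 with an estimated correlation), though 0 of 13 passed singly and 4 did adjusted over the list alone. DESeq2 called 52 genes, and the fit with the mouse as a block, which uses the pairing of tissues, called 45. Median and list test differed in sign here for the cholesterol, inflammatory monocyte and T and NK marker lists, in treated mice for the chemokine, inhibitory receptor, interferon and inflammatory monocyte lists, and in the interaction for the adhesion and Kupffer identity lists. With CD8 T cells taken by their own UMIs 723 passed, and 0 did in thinned sums, in one fit of all groups, with at least 50 cells, with at most 10% mitochondrial counts or at resolution 2.0. The count was 0 without control liver replicate 2, where Maf was log2 2.05 (adjusted p = 0.673), Junb -2.05 (0.388) and Cct6a -1.24 (0.292). It was 11 without control liver replicate 3, where Junb (adjusted p = 0.14), Cct6a (0.165) and the residency list (0.0674) did not pass. It was 1 without control blood replicate 1, where Maf (0.0755) and Cct6a (0.0651) did not pass, 14 without replicate 2 and 20 without replicate 3.

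In treated mice 3 of 8656 genes passed, all higher in liver (338 unadjusted, DESeq2 19). This fit did not use the pairing of tissues by mouse, and with the mouse as a block 111 passed. Cxcl9 was 0.155 CPM in blood and 25.6 ± 10.3 CPM in liver (3 and 77 UMI, ratio 156, counting interval 51.6 to 775, adjusted p = 0.00119). Mt1 was 1.76 and 53.8 ± 25.7 CPM (log2 4.92 ± 0.51, adjusted p = 0.0044) and Mt2 0.458 and 42.8 ± 29.6 CPM (log2 6.78 ± 0.73, adjusted p = 0.0044), both metallothioneins that bind zinc. In the same libraries Cxcl9 was 7100 ± 2453 CPM in LSEC-like and 30.6 ± 16.1 CPM in B-like cells, a class that should lack it. Mt1 was 75.9 CPM in B-like cells of the liver and 8.35 CPM in those of the blood. In thinned sums 0 genes passed (Cxcl9 and Mt1 adjusted p = 0.999), 7 did without treated liver replicate 1, and 8 did in one fit of all groups.

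The naming of T and NK clusters had no class for resident memory CD8 T cells, so Cxcr6 was counted per cell. Cxcr6 UMIs were found in 28.3% ± 7.92 of CD8 T-like cells of control liver (SD, n = 2; median depth 10344 to 12160 UMI) and in 12.6% ± 4.21 of those of treated liver (n = 3; 9446 to 15084 UMI). These became 6.74% ± 3.10 and 2.43% ± 0.963 after thinning to 1000 UMI, with 1 treated cell left out. B-like cells, a class that should lack Cxcr6, gave 3.27% ± 1.31 in control (6177 to 6323 UMI) and 6.41% ± 1.52 in treated liver (11540 to 15699 UMI), 0.468% and 1.08% thinned with 7 and 3 cells left out. At least 3 of the fixed residency markers, a rule added after seeing the data, had UMIs in 11.3% ± 3.33 of 78 CD8 T-like cells of control liver and in 13.9% ± 11.2 of 257 of treated liver (exact permutation p = 0.9, two-sided). The treated libraries had 26.1%, 11.6% and 4.0%. Among CD8 T cells taken by their own UMIs the shares were 44.6% ± 9.56 of 111 cells in control and 31.9% ± 11.7 of 190 in treated liver (exact permutation p = 0.3). Of 2940 T and NK cells with Cxcr6 UMIs in control liver 62.5% were NKT-like, 26.4% NK or ILC1-like and 0.816% CD8 T-like. Of 4401 in treated liver the values were 43.9%, 22.0% and 0.727%. Unnamed cells held 8.88% in control and 32.3% in treated liver, so these shares also depend on the naming of clusters.

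Every other class with enough cells was tested for the same treatment contrast. In liver, genes passing numbered 5540 in B-like, 348 in CD4 T-like, 2979 in conventional dendritic cell-like, 2932 in Kupffer cell-like, 5188 in monocyte-like, 1472 in neutrophil-like, 4279 in NK or ILC1-like, 4121 in NKT-like and 767 in plasmacytoid dendritic cell-like cells. Kupffer cell-like cells gained Csf3, the granulocyte growth factor (at least 142-fold, 127.6 ± 38.7 CPM against 0 UMI), and monocyte-like cells Timp1, a protease inhibitor (at least 183-fold, 175 ± 61.2 CPM). Neutrophil-like cells gained Saa3 (at least 214-fold, 1820 ± 824 CPM; adjusted p = 0.0674 in thinned sums) and the GTPase Gbp5 (at least 74.2-fold; 0.114 in thinned sums). Conventional dendritic cell-like cells, mostly of cluster 42 in control and cluster 34 in treated liver, lost Dkk2, a Wnt inhibitor, to 0 UMI (at least 191-fold lower). B-like cells lost Hcrtr2 (175 ± 47.0 to 2.10 ± 0.631 CPM, log2 -6.28 ± 0.30), and NKT-like cells lost the surface receptor Cd7 (86.7 ± 11.5 to 3.31 ± 2.31 CPM, log2 -4.74 ± 0.37). In blood, genes passing numbered 6154 in B-like, 2469 in CD4 T-like, 1833 in conventional dendritic cell-like, 5711 in monocyte-like, 2740 in neutrophil-like, 3805 in NK or ILC1-like and 4513 in NKT-like cells. NK or ILC1-like cells of the blood gained the activation antigen Ly6a (5.99 ± 2.98 to 936.4 ± 249 CPM, log2 7.27 ± 0.32). Leaving out control liver replicate 2 or 3 gave 218 or 188 genes in CD4 T-like, 1273 or 1151 in conventional dendritic cell-like, 1045 or 1064 in Kupffer cell-like cells. It gave 3212 or 3398 in monocyte-like, 455 or 568 in neutrophil-like, 2202 or 1863 in NK or ILC1-like, 1670 or 1444 in NKT-like and 275 or 135 in plasmacytoid dendritic cell-like cells. Leaving out treated liver replicate 3 gave 196 genes in CD4 T-like cells, and leaving out treated liver replicate 1 gave 413 in plasmacytoid cells. In blood, leaving out control replicate 1 gave 1628 genes in CD4 T-like cells, control replicate 2 gave 719 in conventional dendritic cell-like and 1628 in neutrophil-like cells, and control replicate 3 gave 703 in conventional dendritic cell-like cells.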

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

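The interaction tests in classes other than CD8 T cells and the tests on the T and NK cluster weighed here were chosen only after the results were seen. The list tests in CD8 T-like cells were planned.

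In CD8 T-like cells 7 gene lists differed between tissues in their response to ethanol plus LPS, by camera on the interaction at the preset correlation. The log2 change was lower in liver than in blood for residency genes (adjusted p = 0.0178), circulation genes (adjusted p = 0.0112), interferon-stimulated genes (adjusted p = 0.00796), LSEC identity genes (adjusted p = 4.25e-06) and mitochondrially encoded genes (adjusted p = 0.0240). It was higher in liver for MHC class I genes (adjusted p = 0.0240) and for immediate early and heat shock genes (adjusted p = 0.0365). With an estimated correlation none of the 26 lists tested passed. For the LSEC identity list a T cell response and LSEC RNA cannot be told apart, since the LSEC marker Stab2 in these sums was 25.3 and 3.29 CPM in control liver, at most 1.69 CPM in treated liver and at most 0.445 CPM in blood. Without control liver replicate 3 the residency (0.551), circulation (0.438), interferon (0.920, opposite direction), immediate early (0.551) and mitochondrial (0.195) lists did not pass, and without control liver replicate 2 the LSEC identity (0.112), MHC class I (0.172) and mitochondrial (0.112) lists did not. Treated liver replicate 1 decided the circulation (0.0551), interferon (0.429) and mitochondrial lists (0.0897), and treated liver replicate 3 the residency (0.12), MHC class I (0.415), immediate early (0.226) and mitochondrial lists (0.0574). Among blood libraries, leaving out control replicate 1 ended the mitochondrial call (0.112), control replicate 2 the immediate early call (0.722) and control replicate 3 the MHC class I call (0.0515). Leaving out treated blood replicate 1 ended the MHC class I (0.0964) and immediate early calls (0.458), treated replicate 2 the MHC class I (0.165) and mitochondrial calls (0.441) and treated replicate 3 the interferon call (0.147). With the mouse as a block the residency list had an adjusted p of 0.0766.

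In conventional dendritic cell-like cells 2 genes differed between tissues in their response by edgeR's interaction test, Atxn1 (log2 -4.99 ± 0.61) and the IL-7 receptor gene Il7r (log2 -3.24 ± 0.37), each with a lower log2 change in liver than in blood. In NK or ILC1-like cells 11 genes differed. The log2 change was higher in liver than in blood for 7, among them the metallothionein Mt1 (log2 4.03), the early response gene Nr4a1 (log2 3.17) and Cpne7 (log2 2.31), and lower for 4, Mmp9 (log2 -3.46), Ly6a (log2 -3.63), Pvr (log2 -2.30) and Gimap7 (log2 -1.30). Liver and blood cells of this class lay mostly in different T and NK clusters, 9 and 6 in control and 8 and 2 in treated mice, so the differences may be between populations. RNA from other cells may also enter, which was not tested for these genes. Mmp9 is a fixed marker of neutrophil-like cells, which were 36.6% of named immune cells in treated blood and 14.3% in treated liver. Mt1 was also higher in B-like cells of treated liver than in those of treated blood. With the mouse as a block the counts were 57 in dendritic and 307 in NK or ILC1-like cells, and with DESeq2 76 and 61. In B-like, CD4 T-like, monocyte-like, neutrophil-like and NKT-like cells edgeR called 0 genes each, with 431, 548, 486, 709 and 331 at an unadjusted p under the threshold and 1, 0, 2, 21 and 1 called by DESeq2. With the mouse as a block edgeR called 1, 1, 2, 5 and 4.

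Unnamed clusters with at least 50 cells in treated liver and none in control liver held 483 (cluster 33), 214 (cluster 37), 122 (cluster 48), 361 (T and NK cluster 18) and 100 cells (T and NK cluster 22). The first is the one kept out of the LSEC-like class by its leading genes.

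T and NK cluster 18, with 54 more cells in treated blood, was weighed. Of its cells 90.8% had UMIs of Cd3e, 79.8% of the T cell receptor gene Trac, 61.7% of Cd8a and 84.8% of Cxcr6. Itga1 UMIs were in 88.7% (2.01% of CD8 T-like cells of treated mice) and Itgae UMIs in 4.82% (3.66%). The NK receptor gene Ncr1 had UMIs in 53.3% (5.24% of CD8 T-like cells of treated mice). With T cell genes and Ncr1 both frequent, it is not called a T cell or an NK cell cluster here. Doublets with CD8 T cells are argued against, since the cluster had 2.42 Cd8b1 UMIs per 100 Cd8a UMIs and CD8 T-like cells of treated mice, blood and liver together, had 146. Cells with Cd3e, Cd8a and Cxcr6 and no Cd8b1 UMIs were present in control liver at 2.68% ± 0.199 of T and NK cells (n = 2), against 4.95% ± 1.18 in treated liver (n = 3), 0.528% ± 0.0764 in control blood and 0.945% in treated blood. In control liver 79 of 99 such cells lay in T and NK cluster 9, named NK or ILC1-like, and in treated liver 177 of 284 in cluster 18. A candidate explanation is thus a treatment response that set cells already present in control liver apart as a cluster, which the 2.68% allows and does not prove. Recruitment of such cells was not tested and stays open.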

How the results depend on the processing

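Alternative doublet thresholds, excluded clusters put back, CD8 T cells taken by their own UMIs, the per-cell gates, Il15 levels without each library and interactions outside CD8 T cells were tests added after seeing the data; the other settings were planned. Of the tested values of single genes and lists under alternatives, 10470 were kept, 372 lost and 236 gained a call, 55 moved and 14 reversed. A turn of sign counted as a reversal only where the value passed in the main or the alternative setting. Values that passed in neither counted as kept whatever their direction. Of the summary counts, shares and levels, 647 were kept, 56 lost and 4 gained a call and 64 moved. The NKT-like share in blood, which did not pass, ranged from log2 -0.90 to 1.18 when each library was left out. With RLE size factors 512 values of genes and lists were kept and 2 gained a call. Where no cause is named below, the cause was not tested. At a simulated 2-fold change 21% of genes were recovered in liver sums of CD8 T-like, 12% of CD4 T-like, 6% of Kupffer cell-like and 2% of neutrophil-like cells, and the cause of the differences was not tested. Control liver had 2 libraries, and leaving one out leaves a lone sample that is assumed to vary like the other group.

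Sums thinned to the smallest library, with less depth by construction, called 1205 genes in LSEC-like cells, 199 in CD8 T-like cells of the liver and 1275 of the blood, 0 between tissues in control and 0 in treated mice, and 18090 and 10409 over the other classes of liver and blood. At most 10% mitochondrial counts gave 405 genes in CD8 liver and 0 between tissues in control mice. DESeq2 called 52 genes between tissues in control mice, 19 in treated mice and 2 for the interaction, and no filter on low counts 145, 94 and 8. One fit of all groups called 0 and 8 between tissues, at least 50 cells 0 and 7. CD8 T cells by their own UMIs gave 723 between tissues in control mice and 7 for the interaction. With an estimated correlation 0 gene lists passed in each of the 6 main comparisons.

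With the mouse as a replicate block the counts were 45 between tissues in control mice, 111 in treated mice and 9 for the interaction. Of the single genes and lists of all comparisons, 632 kept their side of the threshold, 9 lost and 40 gained a call and 1 moved with a replicate block. These include treatment contrasts within a tissue, where the block was the shared number and not a mouse. Shared numbers do not pair control with treated mice (correlations 0.0532, 0.0993 and -0.100 in blood CD8 T-like cells and -0.0262 in liver). A block on them left 3 liver shares passing, with B-like -1.61 (adjusted p = 0.0638), CD8 T-like 2.00 (0.0736), Kupffer 1.10 (0.310), neutrophil-like 3.36 (0.0786), plasma cell -1.27 (0.528) and plasmacytoid -1.57 (0.0860) not passing, and B-like in blood at -1.95 passing (0.0319).

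Log2 changes of liver shares that lost their call were as follows. At resolution 2.0, with 4 shares passing, CD4 T-like was -0.81, CD8 T-like 0.98, Kupffer 1.10, monocyte 1.04 and plasma cell -0.94. With a TMM-normalized offset, with 5 passing, basophil was 3.49, CD8 T-like 1.43, Kupffer 1.19 and plasma cell -1.83, while plasmacytoid cells in blood gained a call at -2.51. Without neutrophils in the denominator CD4 T-like was -0.97 and plasma cell -1.66, and in blood 0 shares passed, with CD4 T-like at -1.71. Doublets kept gave Kupffer 1.17 and at least 500 genes gave plasma cell -1.50. Excluded clusters put back gave CD8 T-like 1.48 and Kupffer 1.17. A doublet score of at most 0.15, with 3 passing, gave basophil 6.74, CD4 T-like -1.15, CD8 T-like 1.55, Kupffer 1.29, monocyte 1.15 and plasma cell -2.33, and automatic thresholds gave CD8 T-like 1.56 and Kupffer 1.17. Il15 in CPM moved at resolution 2.0 to 60.5 in LSEC-like and 14.6 in NK or ILC1-like cells of control liver and 5.92 in the latter of treated liver, and with excluded clusters put back to 5.40 in CD4 T-like cells of control liver. A gate of 3 or more residency markers gave a difference of 2.62 percentage points between treated and control CD8 T-like cells.

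Leaving out each library gave 2278 to 5520 genes in LSEC-like cells, 276 to 1239 in CD8 liver, 2190 to 3784 in CD8 blood, 0 to 20 between tissues in control and 3 to 7 in treated mice, 0 to 1 for the interaction, 13610 to 27482 over the other liver classes, 3 to 8 interaction lists, 2 to 6 liver shares and 0 to 3 blood shares. Liver share changes ranged for B-like from -2.29 to -1.57, basophil 3.15 to 4.25, CD4 T-like -1.39 to -0.92, CD8 T-like 1.17 to 2.00, Kupffer 0.88 to 1.62, monocyte 1.00 to 1.39, plasma cell -2.66 to -0.30 and plasmacytoid -2.19 to -1.50. Blood share changes ranged for B-like from -2.38 to -1.30, CD4 T-like -2.56 to -2.16, neutrophil-like 3.31 to 4.09 and plasmacytoid -3.42 to -1.11.

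Reversed values were Cx3cr1 in LSEC-like cells in thinned sums (-0.17). With CD8 T cells by their own UMIs they were Cd160 in liver (-1.41), Cxcr6 in blood (0.17) and, between tissues in control mice, Ccl4 (4.77), Pecam1 (-0.62), Stmn1 (2.39) and Hmgb2 (1.74). Lists also turned direction when a library was left out. Between tissues in control mice, cytotoxicity turned without control liver replicate 3 (adjusted p = 0.0322; range over the libraries left out 0.000394 to 0.839), and so did interferon (0.996; range 9.58e-09 to 0.996). In the interaction interferon turned without the same library (0.920; range 3.58e-06 to 0.920). Between tissues in treated mice interferon turned without treated blood replicate 3 (0.0277) and treated liver replicate 1 (0.000949), with a highest value of 0.460. LSEC identity turned without the same libraries (0.794 and 0.950), with a lowest value of 0.0785.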

Other observations

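The comparisons of split libraries, also by the mice they part, the bounds on RNA from other cells and the checks of Il15 in neutrophil-like cells were tests chosen only after the results were seen.

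The fixed gene lists were also tested in the other immune classes. With an estimated correlation 2 lists passed in CD4 T-like cells of the blood and 0 in each of the other classes tested. In CD4 T-like cells of the blood all 24 interferon-stimulated genes rose, also adjusted over the list alone (median log2 3.43, adjusted p = 4.52e-116; adjusted p = 0.0489 with an estimated correlation). In neutrophil-like cells of the liver 22 of 23 rose (23 adjusted over the list alone; median log2 4.20, adjusted p = 7.4e-36, adjusted p = 0.267 with an estimated correlation). Kupffer cell-like cells gained 24 of 25 NF-kB and LPS response genes (25 adjusted over the list alone; median log2 3.58, adjusted p = 1.31e-24, adjusted p = 0.1 with an estimated correlation). Conventional dendritic cell-like cells of the liver gained 9 of 12 IL-15 axis genes, also adjusted over the list alone (median log2 1.96, adjusted p = 5.27e-08, adjusted p = 0.175 with an estimated correlation). B-like cells of the liver gained 10 of 12 cell cycle genes (11 adjusted over the list alone; median log2 2.82, adjusted p = 6.5e-05, adjusted p = 0.382 with an estimated correlation) and monocyte-like cells 11 of 13, also adjusted over the list alone (median log2 2.85, adjusted p = 0.000531, adjusted p = 0.558 with an estimated correlation). Monocyte-like cells also gained 13 of 13 glycolysis and hypoxia genes (adjusted p = 6.78e-11, adjusted p = 0.186 with an estimated correlation).

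The effects in blood and liver, which come from the same mice, overlapped within other classes. In B-like cells 2592 genes were higher in both tissues, where independent lists would share 822, and 2002 lower in both against 595. In monocyte-like cells the values were 2311 against 698 and 2028 against 588, in NKT-like cells 1652 against 401.5 and 1618 against 399, in NK or ILC1-like cells 1477 against 365 and 1274 against 319, and in neutrophil-like cells 740 against 176 and 408 against 67.9. Neutrophil markers rose in the sums of several classes that should lack them, 6 of 6 in NKT-like and 6 of 6 in NK or ILC1-like cells of the liver (median log2 4.88 and 4.84, adjusted p = 0.411 and 0.340 with an estimated correlation).

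The first pattern weighed was the rise of leukocyte and inflammatory genes in LSEC-like cells. Neutrophil-like, monocyte-like, Kupffer cell-like, conventional dendritic cell-like, NKT-like, NK or ILC1-like, CD8 T-like and B-like cells were each given the largest share of the treated LSEC-like sums that the levels of their own abundant markers there allow, and the whole profile was scaled by that share. CD4 T-like, plasmacytoid, plasma and basophil or mast cells and the unnamed cells (31.0% of treated liver) were given no bound. For the IL-15 axis genes that rose, the bounded classes can bring at most a median of 7.08% of the level (Il15ra 9.17%, Il2rg 9.66%, Mcl1 5.00%, Socs1 3.64%), which argues against these classes as their main source and leaves the others open. For the inflammatory monocyte list the bound was 83.7% and for the cytotoxicity list 72.2%, so there RNA from other cells and expression by LSECs cannot be told apart, since the bound leaves room for most of the level. Cd14 (7.48%) and Serpinb9 (7.16%) had low bounds within these lists.

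The second pattern was Il15, highest in neutrophil-like cells of control liver and lower after ethanol plus LPS. For the high control level, low total RNA as the whole cause is argued against. A neutrophil-like cell of control liver held 2.99 times the Il15 UMIs of an LSEC-like cell. Its total UMI was 4517 against 10971, so part of the lead in CPM over LSEC-like cells goes with less RNA per cell. Free RNA is argued against by a ratio of 189 to the level in B-like cells. For the fall, Il15 UMIs per cell went from 2.07 ± 0.676 to 0.815 ± 0.123 while total UMI per cell went from 4517 to 10112, so part of the fall in CPM goes with more RNA per cell and its size beyond that was not tested. Dilution by immature neutrophils as the whole cause is argued against, since the treated liver cluster not led by granule genes had 100.6 CPM while the lowest control library had 369 CPM. Less Il15 RNA per neutrophil, more total RNA per cell and a change in which neutrophils are in the liver may each contribute and stay open, with 72 control cells.

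Splits of the 6 libraries of a comparison into 3 and 3 number 10, too few for a share under 0.05, and in each comparison 1 of the 10 splits, the real one, reached the real count. Real counts and the highest of the other splits were 3361 and 0 for CD8 T-like cells of the blood, 6154 and 0 for B-like, 2469 and 0 for CD4 T-like, 5711 and 0 for monocyte-like, 2740 and 0 for neutrophil-like, 3805 and 0 for NK or ILC1-like and 4513 and 0 for NKT-like cells of the blood. For treated CD8 T-like cells between tissues the numbers pair the libraries. Of the 4 splits that part all 3 mice the real one called 3 genes and the highest of the others 0, or 111 and 0 with the mouse as a block. The 6 splits that part 1 mouse called at most 1, and 4 splits are too few for a share under 0.05.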
